A study of Mus musculus with 8 samples.

How the data were processed

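RNA sequencing was performed on undifferentiated spermatogonia sorted from adult mouse testes, with 4 samples of genotype Tert CreER/flox and 4 of genotype Tert CreER/+, all carrying a tdTomato reporter. Per the labels' protocols, libraries were made from column-purified total RNA with a stranded, low-input total RNA kit, which keeps transcripts without a poly(A) tail. The submitters' processing notes name Trim Galore, TopHat2 2.0.4, Bowtie2 2.0.0-6, Bowtie and DESeq2 with the builds mm10 and GRCm38. The program that counted reads per gene, its strand setting, the annotation and the treatment of reads that map to several places are not given in the sources used here.

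The values came from a single table in which the authors compared the groups, and values per library were not used here. In this table the authors' deposited mean count is a normalized count signal averaged over all libraries. Its fold changes and their standard errors (SE) are log2 values fitted by the authors. The deposited test score is the Wald statistic, which differed from the log2 fold change divided by its SE by at most 2.58e-07 in any row. The p-values deposited by the authors matched a normal distribution of that statistic to within 0.424%, and their adjusted p-values matched a Benjamini-Hochberg adjustment over the rows of the table to within 0.426%. Fold changes were read as flox over CreER/+, because the table is named as flox against WT. The labels have no wild-type group, and the sign could not be checked against the targeted gene.

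The table held 14853 rows, each keyed by an Entrez gene ID. For 14828 rows the ID matched a RefSeq gene of assembly GRCm38.p6, whose symbol and coordinates were used, since 1183 rows lacked a symbol and 432 carried a symbol other than RefSeq's. Rows that share their values with another row numbered 138, as copies of a gene that received the same reads would. Every mean count was above 10. The total count of each library was not used here, so depth is given only as mean counts and SEs. The mean counts summed to 9627624 with identical rows counted once. The median SE of the log2 fold change was 0.56 for mean counts over 10 up to 20, 0.17 for those over 100 up to 300 and 0.08 above 1000.

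No model was fitted across libraries. A gene was called changed at a deposited adjusted p under 0.05. Of 36 gene lists fixed before the data were examined, the 34 with at least 3 measured members were tested with cameraPR of limma 3.58.1 in R 4.3.3. This test asks whether the Wald statistics of a list lie above or below those of the other genes. It was two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. A correlation estimated from the libraries was not used here, and a preset value of 0.05 was the stricter alternative. Beside it stand the members called over all genes, the members past 0.05 when adjusted over the list alone, and the percentile of the list's median log2 fold change among 10000 random lists of the same size matched on mean count. Fisher's exact test, two-sided, compared list membership with being called higher or lower. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

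Named genes followed a rule fixed before the data were examined. It took Tert, Myc, Mycn, Gfra1, Kit and Cdkn1a, the 8 genes of smallest adjusted p in each direction, and the 6 largest folds in each direction among called genes with a mean count of at least 50. In each list it took up to 4 called members, or where none was called up to 2 of smallest p, named only in the account of that list. Genes that carry only a predicted-gene number were counted and need not be named. Myc was not analysed here.

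Alternatives fixed beforehand were other thresholds, a minimum fold, adjustment over other gene sets, a t distribution with 6 degrees of freedom, a null SD estimated from the central statistics, centring of the fold changes, and other settings of the list test. Added after the data were seen were counting identical rows a single time, leaving out short non-coding RNAs, leaving out genes whose SE was over 1.5 times that of genes of like mean count, and removing a fitted trend with transcript length, GC content and mean count. Lengths came from the longest GENCODE M21 transcript, which was found for 99.2% of rows. The trend was fitted to, and removed from, 13726 protein-coding rows only.

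The steps were tested on simulated data with the SEs of this comparison and 14853 genes, 200 of them changed. At a log2 fold change of 0.5, 41% of the changed genes were recovered, and 71% at a log2 fold change of 1, with 6 unchanged genes called. The list test called 4.26% of 680 simulated lists without an effect at an unadjusted p under 0.05. Those lists held independent draws from a standard normal distribution. They do not show how the test behaves with correlated genes or with statistics wider than that distribution.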

Results

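Gene expression was measured by total RNA sequencing in undifferentiated spermatogonia, the testis cells that include the stem cells of the male germline. The mice, of strain C57BL/6 and 8 to 12 weeks old, carried at the Tert gene either CreER opposite a loxP-flanked allele (CreER/flox, 4 samples) or CreER opposite a normal allele (CreER/+, 4 samples). The sample titles call the CreER/flox group TERT-del and the CreER/+ group TERT-hetero. Tert encodes the reverse transcriptase subunit of telomerase, the enzyme that extends chromosome ends. CreER is a Cre recombinase that becomes active with tamoxifen, and tdTomato is a red fluorescent protein that Cre switches on. On day 7 after tamoxifen, cells with high surface MCAM, no KIT and tdTomato fluorescence were sorted. All gene values below are those of the authors' comparison of the groups, given as log2 fold change of flox over CreER/+ with its SE. The median gene had a mean normalized count of 192, and the total count of each library was not used here.

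The targeted gene was examined first. Tert (Entrez gene 21752, chromosome 13, 73626911 to 73649843 in GRCm38) had a log2 fold change of 0.29 (SE 0.26, adjusted p 0.595) at a mean normalized count of 98.0 in the authors' deposited table, and did not pass the test. The part of Tert that Cre removes is not given in the sources used here, so reads from the remaining exons could count for the gene in both genotypes, and this value checks neither the labels nor the sign of the comparison. Terc, the RNA template of telomerase, likewise was not called in the authors' deposited table (0.20, SE 0.23, adjusted p 0.710).

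The main comparison asks which transcripts differ between CreER/flox and CreER/+ spermatogonia 7 days after tamoxifen. In the authors' deposited table, 796 of 14853 genes (5.36%) passed an adjusted p of 0.05, of which 288 were higher and 508 lower in the flox samples. The lower genes fell further, with a median log2 fold change of -0.99 against 0.45 for the higher genes, and were less abundant, with a median mean count of 140 against 560.4. As groups, genes of spermatids, the haploid cells that form sperm, were lower, and ribosomal protein genes and cell cycle genes were higher.

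Among the higher genes, the smallest adjusted p in the authors' deposited table belonged to H19, an imprinted non-coding RNA on chromosome 7 (142575530 to 142578146), which was 1.45-fold higher (log2 fold change 0.53, SE 0.07, adjusted p 2.21e-09, mean count 1899). Mir5121 rose by 0.69 (SE 0.10, adjusted p 5.94e-09) in the authors' deposited table. Its annotated position on chromosome 7 (45126918 to 45126991) lies inside Rpl13a and overlaps the small nucleolar RNA Snord33, so reads of either could count for it. Rpl13a stood at 0.32 and Snord33 at 1.71 in the authors' deposited table. The authors' deposited table also had higher values for the zinc finger genes Zfp111 (0.85, SE 0.14, adjusted p 4.45e-06) and Zfp93 (1.15, SE 0.21, adjusted p 3.86e-05), which neighbour each other on chromosome 7, for the ribosomal protein gene Rps9 (0.70, SE 0.12, adjusted p 7.06e-06) and for Calm3, which encodes calmodulin (0.37, SE 0.07, adjusted p 6.35e-05). Fcamr and Grap completed this group with log2 fold changes of 4.15 (SE 0.82) and 3.97 (SE 0.81) in the authors' deposited table, at mean counts of 16.6 and 13.1. The largest folds among higher genes with a mean count of at least 50 in the authors' deposited table were mainly those of short RNAs, namely Mir6240 (3.44, SE 0.77), Mir6236 (3.04, SE 0.65) and the small nucleolar RNA Snord110 (3.02, SE 0.84), beside the protein-coding Rnf225 (2.89, SE 0.87) and Fam167a (2.80, SE 0.67). The SEs of these 5 genes were 3.32 to 9.52 times those of genes of like mean count. An annotated small nuclear RNA overlaps Rnf225, so its reads could count for that gene.

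On the lower side, the smallest adjusted p values in the authors' deposited table belonged to Gm3002 (-1.88, SE 0.17, adjusted p 2.81e-25) and other predicted genes at the start of chromosome 14. Named genes that followed in the authors' deposited table were Trim17 (-1.33, SE 0.23, adjusted p 6.42e-06), the testis-enriched Tulp2 (-1.05, SE 0.18, adjusted p 1.52e-05), Iqcf3 (-1.57, SE 0.28, adjusted p 1.83e-05) and Fhad1 (-0.93, SE 0.17, adjusted p 3.14e-05). Eppk1 (-2.20, SE 0.65) and Lpcat2b (-1.68, SE 0.36) were among the largest falls in the authors' deposited table. Of the genes chosen for their role in these cells, none was called in the authors' deposited table. Mycn, a MYC family member, stood at 0.31 (SE 0.10, adjusted p 0.0501), the GDNF receptor gene Gfra1 at -0.10 (SE 0.09), the differentiation marker Kit at -0.29 (SE 0.21) and the p53 target Cdkn1a at -0.10 (SE 0.35), all in the authors' deposited table. Mycn passed when the adjustment covered only genes with a mean count of at least 100 (adjusted p 0.0454). The count of 796 rests on the normal distribution of the DESeq2 Wald statistic, whose bulk was 1.45 times as wide as that distribution. Once this width was divided out, 5 of the genes passed, namely H19, Mir5121, Gm3002, Gm5795 and Gm10413. The Gm genes among them lie at the start of chromosome 14. A t distribution with 6 degrees of freedom left 0 genes (1652 at an unadjusted p under 0.05). Removal of a trend with transcript length, GC content and mean count was done for protein-coding genes only, of which 704 had been called. It left 385 and ended the call of 23 of the 57 called named genes it covered.

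**Figure D1:**
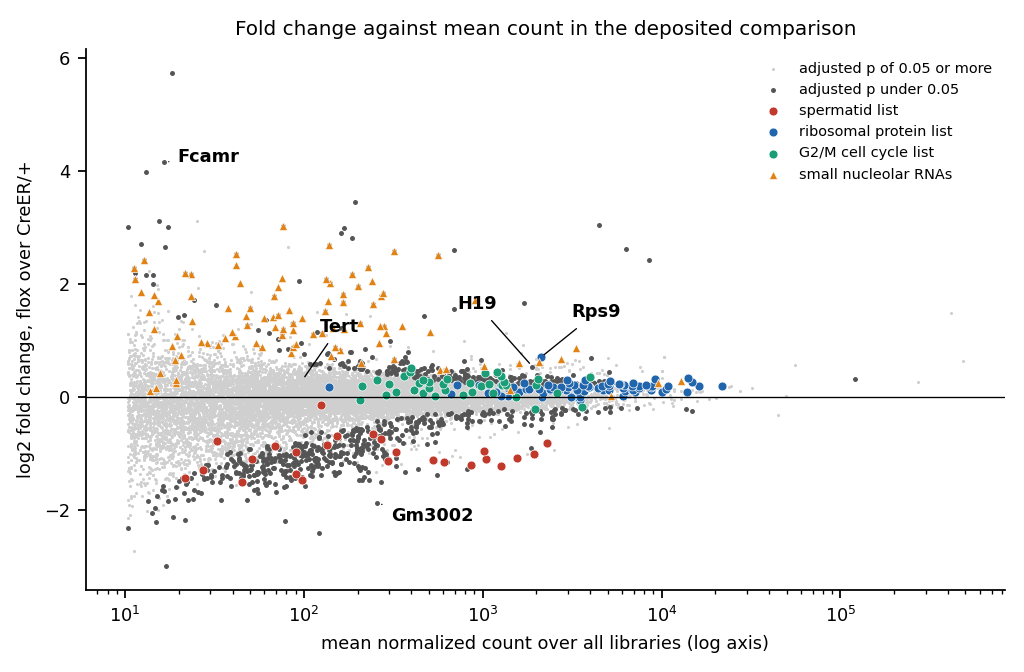
Log2 fold change of flox over CreER/+ (vertical axis) against the mean normalized count over all libraries (horizontal log axis), 1 point per gene, with identical rows drawn a single time. Dark points passed an adjusted p of 0.05, and coloured points mark members of 3 gene lists and the small nucleolar RNAs, which all lie above 0, while the 25 spermatid genes all lie below 0.

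**Figure D2:**
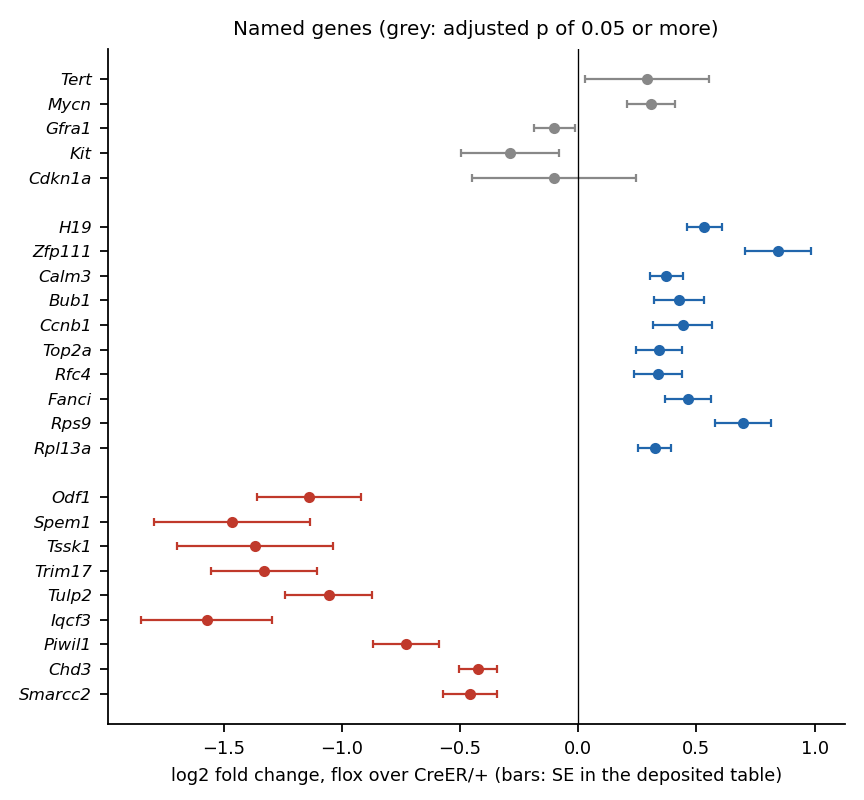
Log2 fold change of flox over CreER/+ for selected named genes in the authors' deposited table, with bars of 1 SE. Tert, Mycn, Gfra1, Kit and Cdkn1a (grey) did not pass an adjusted p of 0.05, whereas the genes in blue were higher and those in red lower.

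Gene lists fixed beforehand asked whether known pathways or cell types moved as groups. Of 34 lists tested with cameraPR, 7 were higher and 2 lower at an adjusted p of 0.05. The strongest fall was that of the spermatid list. All 25 of its measured members were below 0, with a median log2 fold change of -1.09, or 2.12-fold lower (cameraPR adjusted p 1.04e-16), and 10 passed the test over all genes and 23 when adjusted over the list alone. With a preset correlation of 0.05, the cameraPR adjusted p was 3.02e-09. Such list p values compare genes with other genes and do not measure the spread between samples of a group. Its median lay below those of all 10000 random lists. Called members in the authors' deposited table included Odf1, of the outer dense fibres of the sperm tail (-1.14, SE 0.22, adjusted p 0.000125), Spem1 (-1.47, SE 0.33, adjusted p 0.00144), the testis kinase Tssk1 (-1.37, SE 0.33, adjusted p 0.00351) and Dnajb3 (-0.75, SE 0.21, adjusted p 0.0164). The protamine and transition protein genes Prm1 (-1.23, SE 0.45) and Tnp1 (-1.01, SE 0.38), which package sperm DNA, had like values in the authors' deposited table without passing the test (adjusted p 0.0807 and 0.0900). The SEs of the list were 1.53 times those of genes of like mean count (median).

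The list of meiotic spermatocyte genes, the stage before spermatids, did not move as a group (median -0.066, cameraPR adjusted p 0.737). In the authors' deposited table, 2 of its 35 members fell, the piRNA-binding Piwil1 (-0.73, SE 0.14, adjusted p 0.000111) and Sycp2 of the synaptonemal complex (-0.53, SE 0.15, adjusted p 0.0158), and none rose. The lists of undifferentiated, progenitor and differentiating spermatogonia were not called either, with medians of -0.0013, -0.064 and 0.059 and cameraPR adjusted p values of 0.826, 0.602 and 0.811. Their single called gene in the authors' deposited table was the Polycomb gene Bmi1, needed for stem cell maintenance in several tissues (0.29, SE 0.07, adjusted p 0.00643). Among broad germ cell genes (cameraPR adjusted p 0.811), the RNA-binding Dazl was higher in the authors' deposited table (0.23, SE 0.06, adjusted p 0.00997).

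Both cell cycle lists were higher as groups, with few members called singly. The list for DNA replication and the G1/S step had 38 of 39 members above 0, a median of 0.19 and a cameraPR adjusted p of 2.48e-08, with 5 members called over all genes and 10 higher and 1 lower (Tyms) when adjusted over the list alone. The authors' deposited table had increases for Rfc4, a clamp loader subunit (0.34, SE 0.10, adjusted p 0.0233), Pold1, the catalytic subunit of a replicative polymerase (0.35, SE 0.11, adjusted p 0.0374), Gins1 of the replicative helicase (0.51, SE 0.17, adjusted p 0.0404) and cyclin gene Ccne1 (0.60, SE 0.19, adjusted p 0.0425). The G2/M list had 34 of 38 members above 0, a median of 0.21 and a cameraPR adjusted p of 8.58e-07, with 5 members called over all genes and 8 adjusted over the list alone. The checkpoint kinase gene Bub1 (0.43, SE 0.11, adjusted p 0.00464), cyclins Ccnb1 (0.44, SE 0.13, adjusted p 0.0187) and Ccna2 (0.37, SE 0.12, adjusted p 0.0346) and the topoisomerase gene Top2a (0.34, SE 0.10, adjusted p 0.0194) rose in the authors' deposited table. Both lists stayed called under every setting of the list test that was run, but with the trend of fold change with transcript length, GC content and mean count removed, Rfc4, Pold1, Gins1, Bub1, Ccnb1, Ccna2 and Top2a no longer passed. The genes of cyclin-dependent kinase inhibitors and the RB family were not called (cameraPR adjusted p 0.966).

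Lists for ribosomes, translation and growth were also higher as groups by the list test, by smaller folds and with few members called. Of 79 cytoplasmic ribosomal protein genes, 75 were above 0, with a median of 0.16 (1.12-fold, cameraPR adjusted p 1.04e-16), 12 called higher over all genes and 30 adjusted over the list alone. The cameraPR adjusted p of this list was 2.52e-06 with a preset correlation of 0.05. Besides Rps9, the authors' deposited table had increases for Rpl13a (0.32, SE 0.07, adjusted p 0.000712), Rplp1 (0.31, SE 0.08, adjusted p 0.00633) and Rpl22 (0.30, SE 0.08, adjusted p 0.0103). Translation factors had a median of 0.09 (cameraPR adjusted p 4.32e-05), and 3 of 40 were called in the authors' deposited table, namely Eef1b2 (0.28, SE 0.07), Eif2s1 (0.33, SE 0.10) and Eif3e (0.30, SE 0.10). Nuclear genes of oxidative phosphorylation had a median of 0.13 (cameraPR adjusted p 2.50e-05), with 61 of 75 members above 0 and only the ATP synthase gene Atp5h called in the authors' deposited table (0.32, SE 0.10, adjusted p 0.0342). MYC target genes of the nucleolus and growth had a median of 0.09 (cameraPR adjusted p 0.00218), although the only called member in the authors' deposited table, Rabepk, was lower (-0.61, SE 0.18, adjusted p 0.0255). RNA polymerase I and III genes had a median of 0.12 (cameraPR adjusted p 0.0313), with Taf1d called higher in the authors' deposited table (0.38, SE 0.09, adjusted p 0.00319). Annotated small nucleolar RNAs overlap Taf1d, Rpl13a, Eef1b2 and, in the G2/M list, Top2a. Whether their reads count for these genes was not tested. With the length, GC and mean count trend removed, the median of the ribosomal protein list was 0.048 and its adjusted p 0.0128, whereas translation factors (median 0.034, adjusted p 0.364), oxidative phosphorylation (0.058, 0.109), MYC targets (0.069, 0.107) and RNA polymerases I and III (0.072, 0.109) were no longer called. The calls of translation factors, MYC targets and RNA polymerases I and III also ended by random lists (adjusted p 0.457, 0.198 and 0.0773) and with the fold change as statistic (0.233, 0.341 and 0.265), and those of MYC targets and the polymerases with a preset correlation of 0.05 (0.102 and 0.226).

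Genes of chromatin remodelling complexes were lower by a small margin (median -0.09, cameraPR adjusted p 0.0484). In the authors' deposited table, 4 of 30 were called lower, the nucleosome remodellers Chd3 (-0.42, SE 0.08, adjusted p 9.27e-05) and Chd7 (-0.31, SE 0.08, adjusted p 0.0122), Smarcc2 of the SWI/SNF complexes (-0.46, SE 0.11, adjusted p 0.00488) and Bptf (-0.37, SE 0.10, adjusted p 0.0122). The call ended with a preset correlation of 0.05 (adjusted p 0.267), by ranks (0.171), with the fold change as statistic (0.933) and with the trend removed (0.102).

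**Figure D3:**
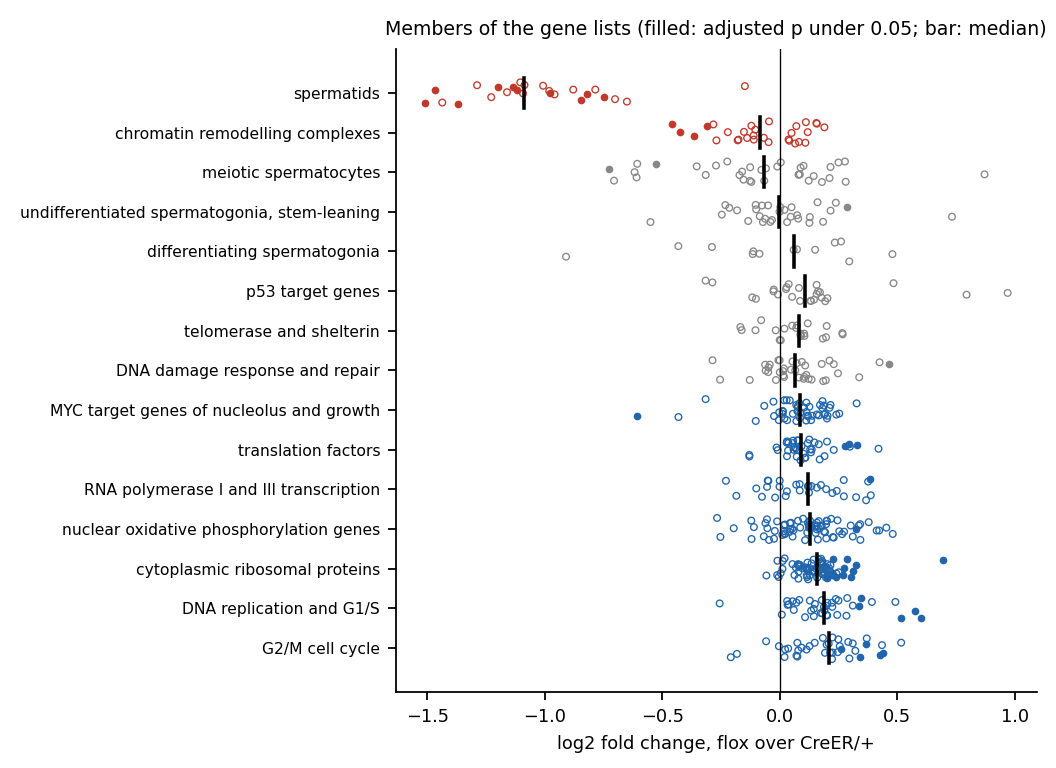
Log2 fold change of flox over CreER/+ (horizontal axis) for each measured member of 15 gene lists, with filled points for genes past an adjusted p of 0.05 and a black bar at the median. Lists called lower are red, lists called higher blue and lists not called grey, and the spermatid median of -1.09 stands apart from the other medians, which lie between -0.09 and 0.21.

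Pathways linked to telomere damage were not called under the main setting. The cameraPR adjusted p was 0.331 for p53 target genes (26 members, median 0.11), 0.331 for telomerase and shelterin genes (22 members, median 0.08) and 0.0835 for the DNA damage response and repair (37 members, median 0.07). The last of these passed with a preset correlation of 0 (adjusted p 0.0298). No p53 target or telomerase gene passed over all genes. The p53 targets of smallest p in the authors' deposited table were Aen (-0.32, SE 0.11), just short of the threshold, and Ccng1 (0.48, SE 0.17, adjusted p 0.0656). Aen passed when the adjustment covered only genes with a mean count of at least 100 (adjusted p 0.0454) and with fold changes centred on their median (0.0494). Fanci, of the Fanconi anaemia repair pathway, was the called repair gene in the authors' deposited table (0.46, SE 0.10, adjusted p 0.000487). Without called members were also the lists of interferon-stimulated genes (cameraPR adjusted p 0.598), NF-kappaB targets (0.715), WNT targets (0.598), retinoic acid response (0.740), the MYC family (0.786) and immediate early genes (0.612).

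Some uncalled lists held single called genes. The authors' deposited table had higher values for Dusp6, a target of growth factor signalling (0.24, SE 0.07, adjusted p 0.0245), and for Calr, an endoplasmic reticulum chaperone gene (0.24, SE 0.07, adjusted p 0.0190). Lower values in the authors' deposited table were those of the stress gene Ddit3 (-0.62, SE 0.20, adjusted p 0.0359), the sterol regulator Srebf2 (-0.31, SE 0.09, adjusted p 0.0148) and the glycolytic genes Hk1 (-0.42, SE 0.12, adjusted p 0.0158) and Pfkm (-0.56, SE 0.17, adjusted p 0.0282). The lists of these genes had cameraPR adjusted p values of 0.715 for GDNF and FGF signalling, 0.235 for the unfolded protein response, 0.146 for cholesterol synthesis and 0.598 for glycolysis, and that of Polycomb and DNA methylation genes was 0.588.

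Markers of other testis cells that a sort could carry were examined the same way. None of the lists for Sertoli, myoid, endothelial, leukocyte and erythroid cells was called, with cameraPR adjusted p values of 0.598, 0.598, 0.966, 0.811 and 0.761. Trf of Sertoli cells was higher (0.62, SE 0.15, adjusted p 0.00255) and Actg2 of smooth muscle lower (-1.17, SE 0.37, adjusted p 0.0340) in the authors' deposited table. The erythroid list had a median of 0.90 over 4 members, none called, and passed by random lists (adjusted p 0.00194), with SEs 3.16 times those of genes of like mean count. Leydig cells had 1 measured member, Star, and mitochondrially encoded mRNAs were not analysed here.

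Fisher's exact test compared the numbers of called members. Of the spermatid list, 10 of 25 members were called lower, against 498 of 14828 other genes (adjusted p 2.81e-07). Called higher were 12 of 79 ribosomal protein genes (adjusted p 1.23e-06), 5 of 39 DNA replication genes (adjusted p 0.0151) and 5 of 38 G2/M genes (adjusted p 0.0151). No other list and direction passed among the 68 tested.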

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

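Removal of the length, GC content and mean count trend, exclusion of short RNAs and of genes with raised SEs, and counting identical rows a single time were chosen after the data were seen. The number of changed genes depended on how the Wald statistic was judged. Against 796 genes (288 higher, 508 lower), an adjusted p threshold of 0.01 left 264 (86 and 178), a threshold of 0.1 gave 1340 (554 and 786) and a log2 fold change of at least 1 left 319 (68 and 251). Adjustment over genes with a mean count of at least 100 gave 609 genes, of which 332 were lower, as fewer genes were tested. An empirical null SD of 1.45 left 5 genes (2 and 3), with 986 at an unadjusted p under 0.05. The cause of the wide statistics was not tested. A t distribution with 6 degrees of freedom left 0 genes (0 higher, 0 lower), with 1652 at an unadjusted p under 0.05. Under the t distribution the smallest adjusted p was 0.434, that of Gm3002, whose Wald statistic was -11.3. In the simulated data it called 23 changed genes where the normal called 112. That simulation drew normal statistics with known SEs, which favours the normal by design, so it cannot say why 0 genes passed here. Removal of the trend covered protein-coding genes only and left 385 (90 and 295), 353 of them shared with the 796. Before removal, 704 protein-coding genes were called (220 and 484, identical rows a single time). The share of higher genes was 23.4% after removal, against 36.2% of the 796 and 31.6% without short RNAs. Part of that fall thus comes from the non-coding rows left out. Trend removal ended the call of 23 of the 57 called named genes it covered, namely Eppk1, Bmi1, Actg2, Dazl, Taf1d, Rplp1, Rpl22, Eef1b2, Eif2s1, Eif3e, Rfc4, Pold1, Gins1, Bub1, Ccnb1, Top2a, Ccna2, Dusp6, Atp5h, Pfkm, Calr, Chd7 and Bptf. The cause was not tested. Adjustment over all rows or over mean counts of at least 10 changed nothing, since no row was removed. Centring gave 793 genes, identical rows a single time 790, no short RNAs 722, and no genes of raised SE 609.

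No list or named gene changed sign with its call. Of 9 called lists, 9 kept their call with a preset correlation of 0, without genes of raised SE and with identical rows a single time, 8 by ranks and at mean counts of at least 100, 6 with a correlation of 0.05 and by random lists, 5 with the fold change as statistic and 4 with the trend removed, where 5 lists were called in all because cholesterol synthesis joined. The DNA damage response and repair joined with a correlation of 0 (adjusted p 0.0298), and the erythroid list by random lists and with the fold change as statistic (0.00194 and 0.0149). The 4 overlaps by Fisher's exact test held at a threshold of 0.1 and at mean counts of at least 100. Tert stayed uncalled under each setting that tested it, which leaves out the adjustment over mean counts of at least 100.

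No paired analysis was possible because the single table used here compares groups and holds no value per library. The labels also name a count table, which was not used here. For the same reason the replicate block, leaving out each replicate, another normalization, a filter on counts per library, regroupings of the samples and an estimated correlation between genes were not run. Depth limits single genes, with a median SE of 0.56 at mean counts over 10 up to 20.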

Other observations

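The gene families, chromosomes and genome windows below, the trend removal, and, among the tests, the between-gene SD of the spermatid list and the meiotic median, were chosen after the data were seen. For the meiotic median the bound first written, -0.54, would have excluded its explanation, and the rule was changed to require an interval above 0 after that outcome was seen. Beyond the fixed lists, families of sperm tail genes were lower in the flox samples. The families named here may carry the same signal as the spermatid list, which holds Catsper1, so they are not separate support for it. Their median SEs were 1.13 (tubulin tyrosine ligase-like genes) to 2.04 (axonemal dynein heavy chains) times those of genes of like mean count. Among genes named as cilia and flagella associated proteins, 26 of 30 were below 0 (median -0.54, cameraPR adjusted p over 21 families 1.10e-08), and 9 were called lower, with Cfap57 (-0.93, SE 0.19) and Cfap58 (-1.37, SE 0.30) of smallest adjusted p in the authors' deposited table. CatSper genes, which form the calcium channel of the sperm tail, were all below 0 (10 of 10, median -0.89, adjusted p 6.31e-07), as were 12 of 13 tubulin tyrosine ligase-like genes (median -0.77, adjusted p 3.90e-07) and 10 of 12 axonemal dynein heavy chains (median -0.77, adjusted p 1.93e-05). Spata genes fell as well (median -0.77, adjusted p 8.69e-10), with 10 of 28 called lower and none higher. Genes called lower were rare on the X chromosome, where 2 of 593 genes were called against 20.3 expected from the share over all chromosomes (Fisher's exact test, adjusted p over 40 tests 1.48e-05). On chromosome 7, which holds H19, Mir5121, Zfp111, Zfp93, Rps9 and Calm3, 34 of 1099 genes were called higher against 21.1 expected. By the same test this did not pass (adjusted p 0.0761).

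On the higher side, histone genes had a median of 0.50 with 62 of 64 above 0 (cameraPR adjusted p 1.92e-12), while in the authors' deposited table H1f5 was called higher (0.56, SE 0.16) and the testis histone H1f7 lower (-1.26, SE 0.26). The histone SEs were 3.51 times those of genes of like mean count. Mage genes were higher (median 0.42, 16 of 19 above 0, adjusted p 3.14e-05), and those called in the authors' deposited table were Magea2 (0.84, SE 0.25), Mageb1 (0.45, SE 0.13) and Mageb2 (0.45, SE 0.13), the last 2 being near-identical copies of uncertain value. The call of the family held with the length, GC and mean count trend removed (adjusted p 0.000158). Mitochondrial ribosomal protein genes had a median of 0.13 (adjusted p 0.000119), with 66 of 78 above 0. Igf2, the imprinted neighbour of H19, was higher like it in the authors' deposited table (0.49, SE 0.11, adjusted p 0.00104).

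The fall of spermatid transcripts carries the largest fold of any called list, in cells sorted as MCAM-high and KIT-negative, a gate that would be expected to remove spermatids, and its most abundant members in the authors' deposited table, Odf2, Tnp1 and Prm2, had mean counts of 2304, 1924 and 1550. The between-gene SD was 0.13 beyond the members' SEs and 0.17 beyond those of genes of like mean count, which is consistent with less RNA from spermatids in the flox libraries, except for Spaca1 (-0.15, SE 0.20) in the authors' deposited table, which lay far from the list median of -1.09. Fewer later germ cells of every stage cannot be told apart from this, because the meiotic list, although its median of -0.066 (95% bootstrap interval -0.16 to 0.08) lies above the level set for a shared fall, -0.54, holds genes that spermatogonia may transcribe already, which would dilute such a fall. Members' SEs were 1.53 times those of genes of like mean count, as spermatid RNA that varies between libraries of a group would give, so chance differences in carry-over may contribute. An effect of genotype on these transcripts or on the number of spermatids remains open and was not tested.

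Short transcripts were higher in the flox libraries: across 7137 protein-coding genes with a mean count of at least 200, the log2 fold change fell with transcript length and with GC content (Spearman's rho -0.30 and -0.28 across genes, which are not independent replicates). Removing length, GC content and mean count together, with no share given to each, took the ribosomal protein median from 0.16 to 0.048 while the list stayed called (adjusted p 0.0128), so such a trend and a ribosomal change cannot be told apart. The trend as fitted is argued against as the whole cause of the DNA replication rise, whose median remained 0.12 of 0.19 with a cameraPR adjusted p of 1.01e-05. A trend of another form was not tested. All 97 small nucleolar RNAs were above 0 (median 1.25, 36 called), with SEs 1.58 times those of genes of like mean count. A rise of like size in the RNA of their 75 host genes as a set is argued against. The host median was 0.13 (95% bootstrap interval over genes, not samples, 0.11 to 0.18) against 0.62. That level is the small nucleolar RNA median divided by 2, by a rule written before the test. Gas5 (1.66) rose like its Snord47 (1.83), whereas Zfas1 (-0.33) did not rise with its Snord12 (2.30). Counts of host RNA do not measure transcription of the hosts, which was not tested. Differences in RNA recovery between libraries, within a group too, and an effect of genotype remain open.

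Genes called lower clustered at the start of chromosome 14, where 17 of 32 genes in the first 10 Mb were called lower (median -1.38) and 1 higher. Of the 17, 14 carry a predicted-gene (Gm) number, and sequences were not compared. The folds of the 17 genes were alike, with a between-gene SD of 0.078 beyond the SEs, as a single signal counted in several near-identical copies would give, although choosing called genes narrows that spread, so the 17 genes may stand for fewer separate changes. Whether they share the spermatid change cannot be told apart from a change of their own, because their SEs were 1.25 times those of genes of like mean count, between the bounds set beforehand. A strain variant at this locus and an effect of genotype were not tested. Of 974 window tests, 3 were called. Besides the start of chromosome 14, the region from 45 to 50 Mb of chromosome 11 was called, with 5 of 24 genes higher.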
